A study of Mus musculus with 2 samples.

How the data were processed

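RNA of mouse hybridoma cells cultured for 4 h with 0 or 5 µg/ml of the peptide BSP-II was labelled with Cy3 and hybridised to single-colour Agilent whole-genome arrays, 1 array per dose. The series' design text speaks of 2 independent experiments with different cells; both arrays used here carry replicate number 1, so each group is 1 array. Both arrays lie on the same slide. Scanner files were made with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The deposited intensity values are of several kinds, per the file headers: the raw median pixel brightness of each spot and of its local background, and a processed signal from which background was subtracted, with its error. The deposited flags (unit "other") are Feature Extraction's calls of saturated spots, outlier spots, spots that are positive and significant, and spots well above background. The deposited value table, on a log2 scale, lists 23296 probes, all well above background on both arrays. Its columns have medians of 2.88 (untreated) and 2.99 (BSP-II). It equals the log2 processed signal plus 1 constant per array, −4.85 and −4.94, to within 0.0001 for 23130 probes (99.3%). The constants lie near the negative of the array medians, 4.88 and 4.97; the scale and direction were thus found from the values, and how the centring constant was set is not given in the sources used here.

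The files name probes by accession and hold no gene symbols. Accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6, used for names alone because the arrays' grid was built on mm9. Of 41163 probes, 25135 (61.1%) matched, giving 17326 genes; 16028 did not and were left out of gene counts.

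The log2 processed signal of each array was reduced by its 75th percentile over unflagged non-control spots, 309 on the untreated array and 356 on the BSP-II array. Control spots and 189 spots flagged as outliers on either array were left out, and spots of 1 probe were averaged. Each gene was represented by its probe with the highest mean level over both arrays. Other probes are given beside named genes detected on both arrays. Differences were taken over the 12882 genes whose probe was well above background on both arrays. Genes above background on 1 array only received a lower bound of the fold from their brightest probe there, and their other probes are not given. Brighter genes are those at or above the median level. Signal over background limits what can be seen. Negative controls had an SD of 6.32 on the untreated array and 2.25 on the BSP-II array, local background had a median of 46 and 37, and the lowest signal well above background was 11.4 and 7.66, as the mean of log2 values over a probe's spots. The number of arrays limits the precision: with 1 per group no p-value or spread between replicates can be given.

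Genes are named by a rule fixed before the data were examined: the 12 highest and 12 lowest brighter genes, up to 4 members of each gene list with the largest difference, the 5 largest bounds each way, and Trp53, Cdkn1a, Mdm2, Myc, Actb and Gapdh. Clone, predicted-gene and locus names were passed over. The rule took 162 genes in its list, fixed and brighter-gene parts, of which the text names most; some are not reported here. The 36 gene lists were fixed at the same time. For each list, the median log2 difference of its measured members (at least 5) was placed among 10000 random lists of the same size drawn from 20 bins of mean level. Lists under percentile 2.5 or over 97.5 are called outside.

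The steps were tested on simulated data built on the 12882 genes. Of 50 genes given a 2-fold difference, 38% were counted as at least 2-fold, and of those given 3-fold or 4-fold, 100%; at 1.5-fold it was 6%. Of 12651 unchanged genes, 17 passed 2-fold. A list of 31 genes shifted by 0.15 reached percentile 100, and 5.5% of 200 unshifted lists lay outside. The simulated noise was normal and independent for each gene, with an SD taken from the spread at its level on these arrays. It held no clustered spots and no genes that vary together, so these shares are not error rates of the real arrays.

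Alternatives planned beforehand were median, quantile and loess scaling, the authors' value table, other filters on dim probes, other rules for several probes of a gene, other size thresholds and other ways to summarise lists. Alternatives added after seeing the data were normexp (offset 50) and the raw signal without background subtraction, both on the median signal because the files hold no mean signal. Also added were subtraction of local medians, over 10 rows and columns to each side, and leaving out clustered spots. A clustered spot had 2 or more others within 3 rows and columns that were at least 2-fold different in a shared direction. Its own value played no part in the call. The planned versions on the mean signal were not run. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.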

Results

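Gene expression was measured in mouse hybridoma cells, antibody-secreting cells made by fusing a B cell with a myeloma cell, after 4 h with or without the bursal peptide BSP-II. The bursa of Fabricius is the organ in which B cells develop in birds, and BSP-II is a peptide of bursal origin. There were 2 arrays: 1 from cells given 0 µg/ml and 1 from cells given 5 µg/ml. Each array carried 45018 spots and 41163 different gene probes, read in 1 colour. On the untreated array 24683 probes were well above background, and on the BSP-II array 27284. No non-control spot was saturated. A gene symbol could be assigned to 25135 probes, which covered 17326 genes, and 12882 of these genes were well above background on both arrays.

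The comparison asked which immune and growth-related genes differed in hybridoma cells exposed to BSP-II. With 1 array per dose, no difference given here has a replicate check, and no test was made. "Higher" and "lower" describe these 2 arrays, as log2 differences of BSP-II minus untreated.

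Glycolytic and hypoxia-responsive genes and the genes of the amino acid response were higher on the BSP-II array, and genes of the cell cycle were lower, all by small amounts. Of the 35 measured genes of hypoxia and glycolysis, 34 lay above the median of all genes, and their median log2 difference was 0.18. Of the 39 genes of G1/S and DNA replication, only 7 lay above that median, and of the 34 genes of G2/M and mitosis, only 4. Among the brighter genes, those at or above the median level, the largest single differences, such as Rpl30 at 0.95 and Vash1 at −1.50, mostly rested on 1 probe each.

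The levels on the arrays were close: across the 12882 genes Pearson's r was 0.995 and Spearman's rho 0.995, with genes not being independent replicates. The median log2 difference was −0.03, the quartiles were −0.19 and 0.11, and the SD was 0.31. In all, 12727 genes (98.8%) lay within 2-fold. At least 2-fold higher on the BSP-II array were 26 genes, and at least 2-fold lower were 129, so that 16.8% of these genes were higher. That share differed under other processing and with another set of genes. It was 29.1% (39 higher, 95 lower) with each array scaled to its median and 30.9% (38 and 85) with loess scaling. With normexp, which used another signal, background correction and scaling, it was 28.6% (8 and 20). In the authors' value table it was 43.2% (38 and 50). That table was scaled nearly as with the median (Cdkn1a at 0.297 and 0.296) but covered only 12424 of the genes. Scaling to the median added 0.12 to every log2 difference. Among the 6441 brighter genes only 1 was at least 2-fold higher and 10 were at least 2-fold lower.

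**Figure D1:**
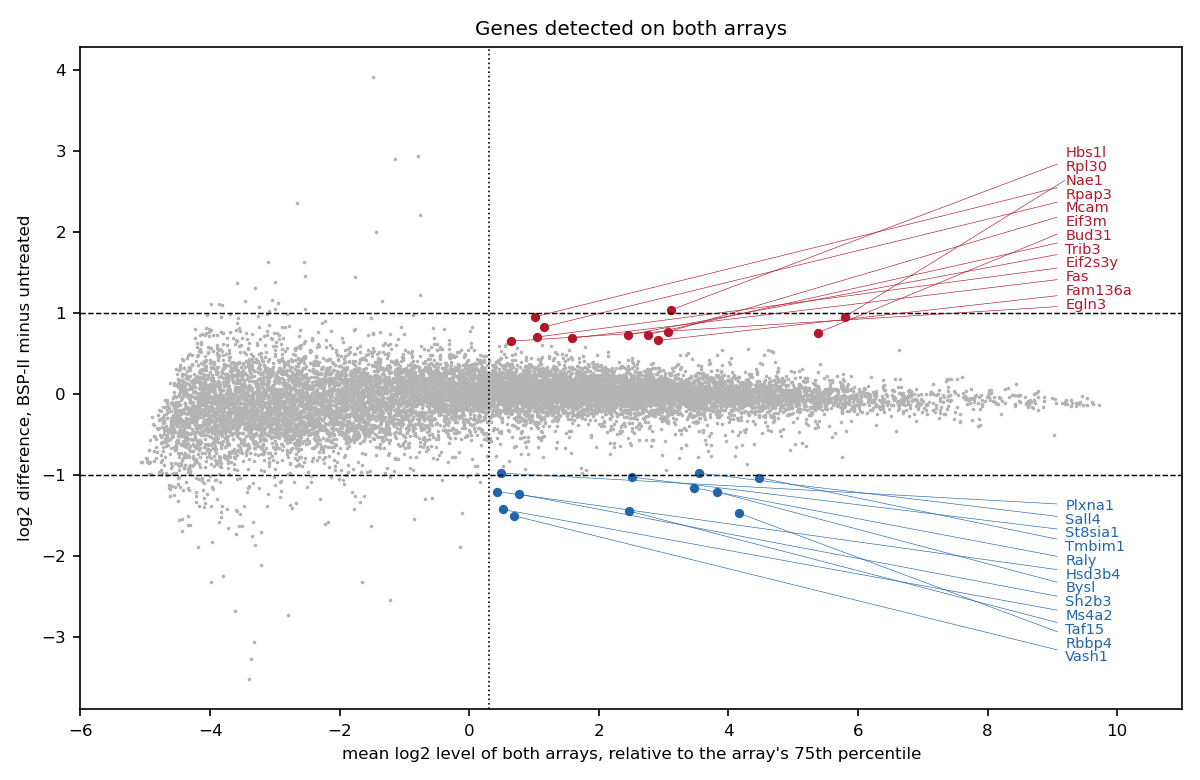
Log2 difference (BSP-II minus untreated) of each gene detected on both arrays, against its mean log2 level relative to the array's 75th percentile; each point is 1 gene. Dashed lines mark 2-fold, the dotted line marks the median level, and the 12 highest and 12 lowest of the brighter genes are named; the points spread more widely at low levels, with an SD of 0.39 below the median level and 0.18 above it.

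Among the brighter genes, the highest on the BSP-II array was Hbs1l, a ribosome rescue factor, which was 2.05-fold higher, with a log2 difference of 1.04, but its other probe gave 0.18. Rpl30, a protein of the large ribosomal subunit, was higher by 0.95, and Eif3m, a subunit of initiation factor 3, by 0.75. Eif2s3y, a Y-linked initiation factor subunit, was higher by 0.70. Nae1, part of the enzyme that activates NEDD8, was at 0.95, and Rpap3, a cochaperone of HSP90, at 0.83. Mcam, an adhesion molecule, was at 0.77, with 0.56 at its other probe. Trib3, a pseudokinase induced by ATF4, was at 0.73, with 0.15 at its other probe. The death receptor Fas, measured by 10 spots, was at 0.69 (1.61-fold). Fam136a was at 0.66. The splicing factor Bud31 (0.73) and the prolyl hydroxylase Egln3 (0.65) were at clustered spots. Such spots had 2 or more others nearby that were at least 2-fold different in a shared direction, whatever the direction of the gene itself.

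The 12 lowest of the brighter genes showed larger differences. Vash1, a tubulin carboxypeptidase, was lowest, with a log2 difference of −1.50 (2.84-fold). Rbbp4, a histone chaperone, was at −1.47, and its other probes gave −1.96 and −0.19. The RNA-binding proteins Taf15 and Raly were at −1.44 and −1.16. Ms4a2, the beta chain of the high-affinity IgE receptor, was at −1.43, and Sh2b3, an adaptor that restrains cytokine signalling, at −1.24. The ribosome assembly factor Bysl was at −1.21, but its other probes gave −0.28 and 0.06. Hsd3b4 was at −1.21 with −0.30 at its other probe, and the sialyltransferase St8sia1 at −1.03 with 0.07. Tmbim1, at a clustered spot, was at −1.03 with −0.21. The transcription factor Sall4 and the semaphorin receptor Plxna1 were both at −0.98.

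Agilent's own per-spot error, carried to a log2 difference, had a median of 0.20. Repeat spots of 1 probe varied less, with a median SD of 0.07 over 159 probes. Both leave out differences between cultures, RNA samples and hybridisations. Of the genes at least 2-fold different, 23 had another detected probe. It went the same way in 17 and was itself 2-fold different in 2 (8.70%), Eno2 and Rbbp4. On the array, 58.1% of the 155 genes had a spot within 3 rows and columns that differed at least 2-fold the same way, against a median of 19.0% for random positions. The lower genes were also unevenly placed: 114 of the 129 (88.4%) lay in the later rows, where 49.2% of all genes lay. Among the gene list members named below, the spots of Birc5, Cd79a, Sos1, Ccl20, Manf, Dhcr7 and Trp53 were also clustered. So was at least 1 of the 10 spots each of Mdm2, Ppia and Actb. Clustering was called whichever way the gene itself differed.

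**Figure D2:**
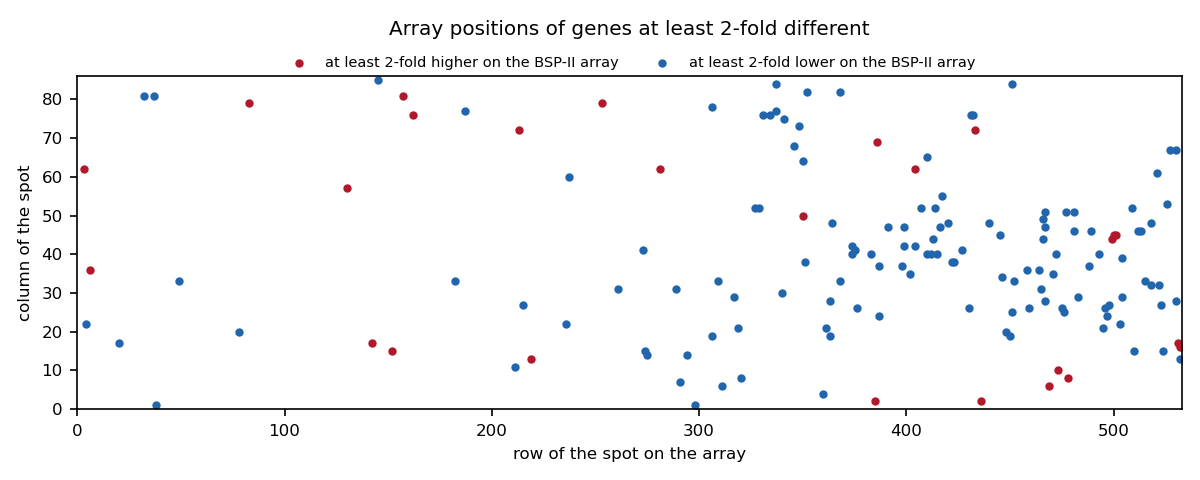
Position on the array, by row and column, of the probe of each gene at least 2-fold higher (26) or lower (129) on the BSP-II array; each point is 1 gene. Of the lower genes, 88.4% sit in the later rows.

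Some genes were well above background on 1 array only, for which only a lower bound of the fold can be given. Such genes numbered 965 on the BSP-II array, 40 of them at least 2-fold above the bound, and 71 on the untreated array, 70 of them at least 2-fold. The bound sets the bright signal against the lowest detected signal of the other array, or the probe's own signal there if higher. That lowest signal was 11.4 on the untreated array and 7.66 on the BSP-II array. With floors this unlike, 40 of 965 and 70 of 71 cannot be set against each other. Loess scaling turned the balance, with 57 genes on the BSP-II array only and 40 on the untreated array only. On the BSP-II array the largest bounds were those of Ap1m2, a subunit of a clathrin adaptor (at least 46.2-fold higher), Slc25a54 (28.0-fold), Prkcq, the theta isoform of protein kinase C (20.9-fold), Atp6v1g3 (17.5-fold) and Inpp4b, a lipid phosphatase (17.1-fold). On the untreated array they were those of Colec12, a scavenger receptor (at least 34.3-fold lower with BSP-II), Papss2 (20.1-fold), Pga5 (16.5-fold), Wnt8a (14.5-fold) and Defb6 (8.73-fold). The spots of Slc25a54, Prkcq, Colec12 and Papss2 were clustered.

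Gene groups were compared through 36 lists fixed before the data were examined. The median of each was set against 10000 random lists matched on level. For 13 lists the median lay outside the middle 95% of random lists, 6 on the high side and 7 on the low side. Genes that vary independently would give 1.8. That number is not a chance rate for these lists, whose genes can vary together and which share members such as Ddit4 and Pdia4. This describes these arrays and does not test the treatment. High and low are meant against the random lists, since scaling each array to its median adds 0.12 to every list and turns the sign of small medians. Low signals are marked for some members below. They also held for Tnfrsf10b, Casp9, Naip5, H1f3, Ccl5, Cd38, Cd79a, Tap2, Cd14, Eif2ak2, Rsad2, Gbp2, Fosb, Agpat2, Scd1 and Cryab.

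**Figure D3:**
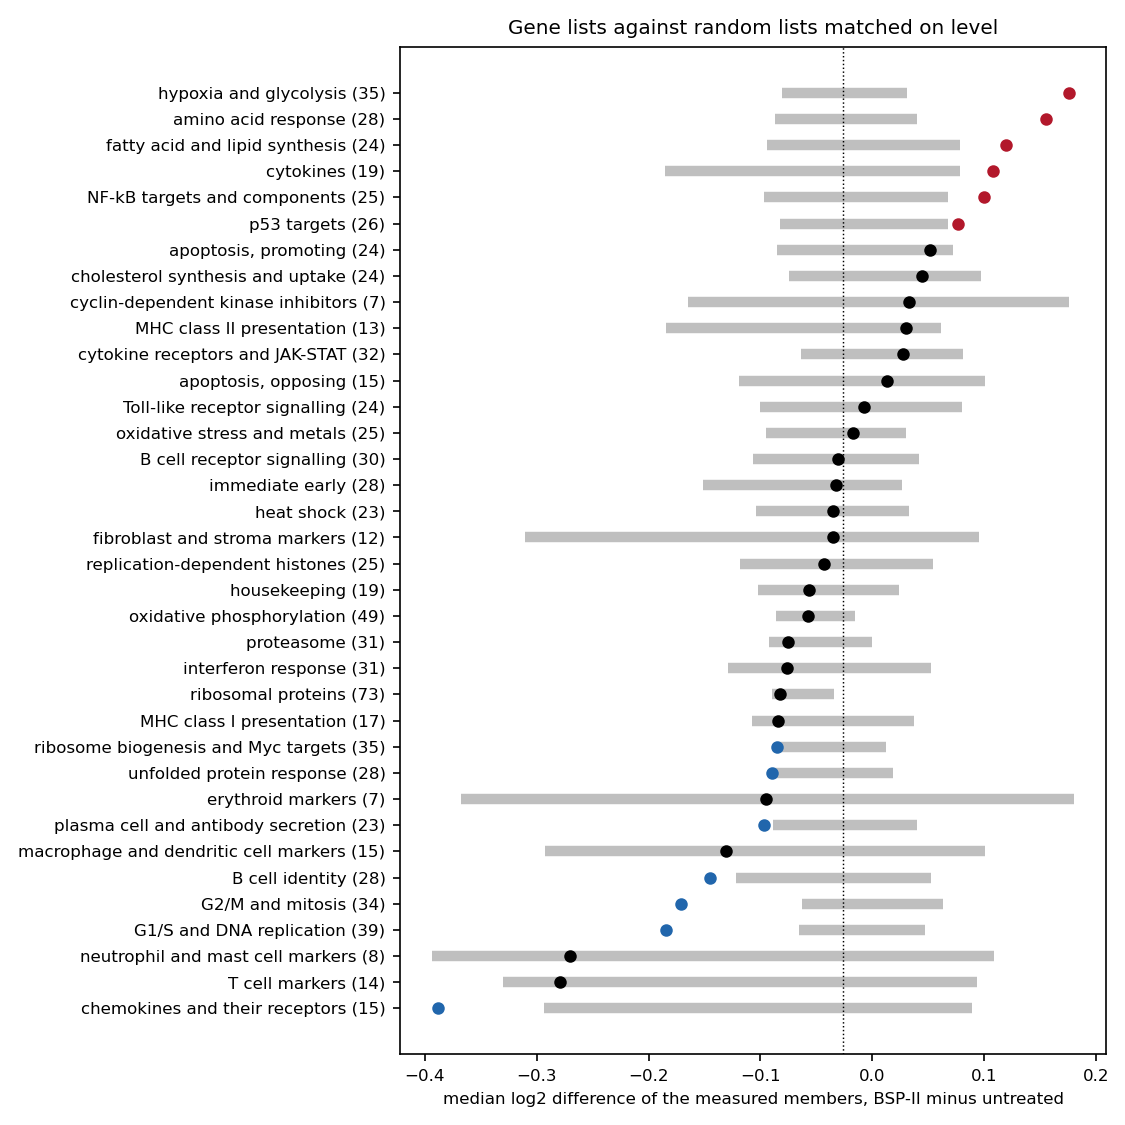
Median log2 difference (BSP-II minus untreated) of each of the 36 gene lists, with the number of measured members in brackets. Grey bars span the middle 95% of random lists matched on level, red and blue points lie above and below it, black points inside, and the dotted line is the median of all genes (−0.03).

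Hypoxia and glycolysis was the highest list, with a median of 0.18 against a random range of −0.08 to 0.03 and a percentile of 100. At least 1.5-fold higher were 3 of its 35 measured genes, and none was 1.5-fold lower. The neuronal enolase Eno2 was 2.06-fold higher at a low signal, from 37.1 to 88.2, with log2 differences of 1.04 and, at its other probe, 1.30. Ndrg1, a stress-responsive gene, was at 0.82, Egln3 at 0.65 and Ddit4, an inhibitor of mTORC1, at 0.54. The amino acid response, genes induced through ATF4, had a median of 0.15 (random range −0.09 to 0.04, percentile 100), with 23 of 28 genes above the all-gene median. Its leading members were the hormone gene Fgf21 (0.82, at signals of 24.5 and 49.9), Trib3 (0.73), the glutathione-degrading enzyme Chac1 (0.54) and Ddit4 (0.54), which both lists hold.

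The 2 cell cycle lists were at the low end. G1/S and DNA replication had a median of −0.18 (random range −0.07 to 0.05, percentile 0). Its leading members were the transcription factor E2f2 (−0.57), thymidylate synthase Tyms (−0.50, and −0.39 at its other probe), the replication licensing factor Cdc6 (−0.38, other probe −0.19) and the replication clamp Pcna (−0.37 over 8 spots). G2/M and mitosis had a median of −0.17 (−0.06 to 0.06, percentile 0), led by the cyclins Ccnb2 (−0.47) and Ccnf (−0.46), the anaphase activator Cdc20 (−0.41) and the phosphatase Cdc25c (−0.36, other probe −0.20). By the chosen probes, no member of either list differed by 1.5-fold or more. Cyclin-dependent kinase inhibitors lay inside their range (median 0.03, percentile 59.7), with Cdkn2a at −0.83 over 10 spots, Cdkn1a at 0.17, Cdkn1b at −0.16 and Cdkn2b at 0.08. Replication-dependent histones were also inside (−0.04, percentile 38.1), with H2ac15 at −0.51, H1f3 at 0.47, H2ac1 at −0.39 and H2ac10 at −0.39 (other probe −0.45).

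**Figure D4:**
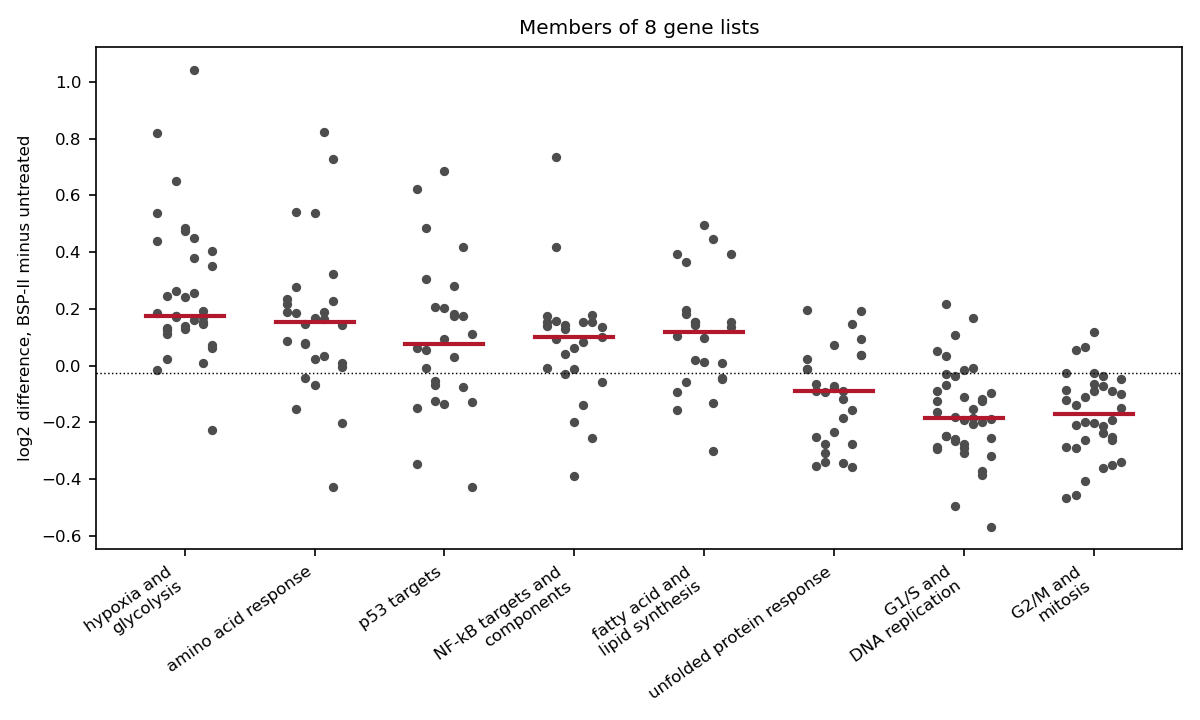
Log2 difference (BSP-II minus untreated) of every measured member of 8 gene lists; each point is 1 gene, red bars are list medians and the dotted line is the median of all genes. Nearly all members of hypoxia and glycolysis (34 of 35) lie above the dotted line and most members of G2/M and mitosis (30 of 34) on or below it.

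Targets of p53 lay just above their range, with a median of 0.08 (−0.08 to 0.07, percentile 98.6) and 17 of 26 genes above the all-gene median. Fas was at 0.69, the membrane protein Perp at 0.62, the death receptor Tnfrsf10b at 0.48 (other probe 0.47) and Sesn2 at −0.43. The call ended when a gene's probes were combined by their median or counted singly. Trp53 itself, which encodes p53, was at −0.13, with 0.02 at its other probe, and its antagonist Mdm2 at −0.13 over 10 spots (other probe −0.19). Promoters of apoptosis (median 0.05, percentile 92.0) and its opponents (0.01, percentile 64.7) were inside. Bmf was at 0.37 with −0.36 at its other probe, Casp9 at 0.30, Tradd at 0.24, Bcl2l2 at 0.38, Naip5 at −0.30, Birc5 at −0.26 and Cflar at −0.26 (other probes −0.50 to −0.13).

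Targets and components of NF-kB were slightly higher as a group (median 0.10, range −0.10 to 0.07, percentile 99.7), with 19 of 25 genes above the all-gene median. The early response gene Ier3 was at 0.74, the inhibitor Nfkbie at 0.42, both at low signals, and the chemokine Ccl5 at −0.39. Cytokines were higher too (0.11, percentile 99.3), with Ltb, a subunit of lymphotoxin, at 0.53 and a high signal. The dim members Tnfsf9, Tgfb2 and Csf3 were at 0.52, 0.47 and −0.55. That call ended in 4 of 15 alternatives: without background subtraction, with no filter on dim probes, among the brighter genes, and with probes combined by their median.

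Chemokines and their receptors had the lowest median of all lists, −0.39 (−0.29 to 0.09, percentile 0.295), from 15 mostly dim genes. Ccl20 was at −0.88, Ccr9 at −0.69, Cxcr3 at −0.66 and Ccl19 at −0.61 (other probe −0.66). Only 3 members had another probe, and the median of those other probes was −0.03, like that of all genes. Olfactory receptor genes, which serve smell, had a like median of −0.33 on these arrays, over 409 genes well above background on both. Its 3 brighter members, named after their values were seen, went both ways: Cxcl16 was at −0.39, Cxcr4 at 0.02 and Ccl25 at 0.15.

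Of the B lineage, the lists of B cell identity and of plasma cells lay on the low side, and B cell receptor signalling lay inside its range. B cell identity had a median of −0.15 (percentile 0.87), with 6 of 28 genes above the all-gene median. The surface protein Ms4a1 (CD20) was at −0.41 and Ikzf1, an Ikaros-family transcription factor, at 0.35. Ikzf3 was at −0.38, at a low signal. The call ended without the filter on dim probes, after local medians were subtracted and with means in place of medians. Plasma cell and antibody secretion had a median of −0.10 (percentile 1.18). Its 23 measured genes held no immunoglobulin heavy or light chain gene. Eaf2 was at −0.86 but at −0.08 by its other probe, Pdia4 was at −0.36, Derl3 at −0.36 and Cd38 at −0.36 with 0.12 at its other probe. The call ended against random lists not matched on level. The unfolded protein response, which serves secretion, had a median of −0.09 (percentile 2.20), with the chaperones Hspa5 and Manf both at −0.34; its call ended in 6 of 15 alternatives. Ribosome biogenesis and Myc targets (−0.08, percentile 2.06) lost its call in 7 of 15, with Ddx10 at 0.32 (other probe 0.04), Polr1b at −0.26, Srm at −0.24 and Nhp2 at −0.21.

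Other immune lists were inside their ranges. B cell receptor signalling had a median of −0.03 (percentile 51.9), with Ptpn6 at 0.38 (other probe −0.02), Cd79a at −0.29 and Sos1 at 0.27 (other probe 0.16). MHC class I presentation was at −0.08 (percentile 9.52; Tap2 0.29, Calr −0.28 with −0.23 at its other probe, Erap1 0.27, Psmb9 −0.26). MHC class II presentation was at 0.03 (percentile 92.4), with dim members that went both ways, such as the costimulatory Cd80 at 0.54 and H2-Aa at −0.56 (other probe −0.46). Cytokine receptors and JAK-STAT were at 0.03 (percentile 65.6), with Stat4 at 0.67, Stat5a at 0.42, Il15ra at −0.46 (other probe −0.10) and the dim Il2rb at −0.81. Toll-like receptor signalling was at −0.01 (percentile 50.4), with Cd14 at −0.69, Tlr9 at −0.50 and Ly96 at 0.35. The interferon response was at −0.08 (percentile 18.4), with Eif2ak2 at 0.44, Rsad2 at −0.42 (other probe −1.18) and Gbp2 at −0.33. Immediate early genes were at −0.03 (percentile 75.1), with Egr3 at −0.97 near background, Ier3 at 0.74, Fosb at −0.45 and Nr4a1 at −0.39.

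Fatty acid and lipid synthesis was the remaining high list, with a median of 0.12 (−0.09 to 0.08, percentile 99.8) and 17 of 24 genes above the all-gene median. Acsl4, which activates long-chain fatty acids, was at 0.50 at a clustered spot (other probe 0.51). The malic enzyme Me1 was at 0.45, Agpat2 at 0.40 (other probe 0.09) and the desaturase Scd1 at 0.39. The call ended among the brighter genes and without background subtraction. Cholesterol synthesis and uptake was inside its range (0.04), with Hsd17b7 at −0.45 (other probe −0.03), Insig1 at −0.40 (other probe −0.13) and Dhcr7 at 0.32 (other probe 0.12). Also inside were oxidative phosphorylation (−0.06, percentile 37.8), ribosomal proteins (−0.08, percentile 7.97), the proteasome (−0.08), heat shock (−0.03, percentile 52.2) and oxidative stress and metals (−0.02, percentile 71.9). Among their members, Ndufs3 was at 0.26, Rpl30 at 0.95, Rps24 at −0.51, Psmd1 at −0.30, Cryab at −0.57, Hmox1, the haem-degrading enzyme, at 0.50 and Osgin1 at −0.81 (other probe −0.10).

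Control genes and markers of other cell types were inside their ranges. Housekeeping genes had a median of −0.06 (percentile 33.0), with Actb at −0.04, Gapdh at 0.06 (other probe −0.04), Ywhaz at −0.25 (other probe 0.04) and Ppia at −0.19. The Actb probe was rather dim, at signals of 218 and 245. Myc was at −0.03, and at −0.04 and −0.03 by its other probes. The signs of Myc and Actb turned with each array scaled to its median, to 0.09 and 0.08. T cell markers had a median of −0.28 (percentile 6.72), macrophage and dendritic cell markers −0.13 (percentile 30.6), neutrophil and mast cell markers −0.27 (percentile 13.0), fibroblast and stroma markers −0.04 (percentile 71.2) and erythroid markers −0.10 (percentile 38.9). Their largest single differences were at low signals. The complement gene C1qc was 3.08-fold higher, from 20.4 to 72.6, and Csf1r was at 0.90 by 1 probe and −0.75 by another. Fcer1g was at −0.91, at signals of 224 and 137. Mcpt4 was at −1.26, Lat at −0.92, Col3a1 at −0.78 and Slc4a1 at −0.49.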

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

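Probes without a gene symbol took no part in the comparisons above. Of the 6554 such probes well above background on both arrays, 29 were at least 2-fold higher on the BSP-II array than on the untreated one, and 133 were at least 2-fold lower. Of the 17911 probes with a symbol, counted singly, 40 were higher and 164 lower. The probes without a symbol were not identified here, and with 1 array per dose the difference was not tested.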

How the results depend on the processing

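Normexp, the raw signal without background subtraction, local medians and leaving out clustered spots were chosen after seeing the data; planned versions on the mean signal were not run, as the files hold none. No paired analysis was possible because the groups share 1 replicate number, with 1 array each. Values of the named genes under alternatives numbered 1864, of which 1788 moved by less than the per-spot error, 76 moved more, and no difference of 2-fold or more changed sign. Smaller ones did so 21 times, in Csf3, Naip5, Tpsb2, Trp53, Gata1, Epor, Actb, Myc, Casp9 and Pdgfrb. The 1788 values say little about stability. The per-spot error had a median of 0.20, while scaling to the median added only 0.12, and some filters leave a gene's value as it was. Of 498 list medians, 406 moved by less than the SD of random lists, 91 moved more and 1 reversed: the unfolded protein response was at 0.0018 relative to all genes without background subtraction (percentile 11.6). Lists outside under every alternative run for them numbered 6 of 13: hypoxia and glycolysis, amino acid response, both cell cycle lists, NF-kB and chemokines, the last in 14 alternatives where the others had 15, since it had only 3 brighter members.

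Counts of genes moved more. The main counts were 26 higher and 129 lower. Genes on 1 array only numbered 40 for BSP-II and 70 for untreated. Loess scaling gave 85 lower and turned that balance, with 57 on the BSP-II array only and 40 on the untreated array only; the next 2 alternatives turned it too. Normexp gave 8 higher and 20 lower (7 and 19 shared with the main counts), an SD of 0.18, and 11 and 4 on the BSP-II or untreated array only. Without background subtraction there were 7, 27, 12 and 6. The authors' table gave 50 lower, all among the 129. With no filter on dim probes there were 228 higher and 546 lower, an SD of 0.53, and 5.26% of 209 genes with a second 2-fold probe. Among brighter genes there were 1 and 10, an SD of 0.18 and 16.7% of 6. Every probe counted singly gave 40 higher, and leaving out clustered spots gave 46 on the untreated array only. A 1.5-fold threshold gave 156 and 625, and 3-fold gave 8 and 25. Taking "positive and significant" as detection gave 103 genes on the BSP-II array only and 154 on the untreated array only. Different thresholds and filters change counts by construction. The authors' table was scaled nearly as with the median, which gave 95 lower. Its 50 lower thus go with the genes it covered, 12424 of 12882, rather than with its scale. For the other alternatives the cause was not tested. Low signals limit the results: the SD of differences was 0.39 below the median level.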

Other observations

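The tests on later rows and on olfactory and vomeronasal receptor genes, the comparison of probes over the same members, and the grouping of genes by symbol, were chosen after the results were seen. Genes sharing a symbol prefix formed 57 families of at least 20 measured members. Of these, 12 had medians outside the middle 95% of random lists, where genes that vary independently would give 2.85. The 5 high ones included zinc finger genes (Zfp, 250 genes, median 0.04 against a random range of −0.05 to 0.01), many of which bind DNA, and Kelch-like genes (Klhl, 27 genes, 0.12), which include adaptors of ubiquitin ligases. Both stayed outside under all 7 scaling, background and position alternatives, although the median of Zfp itself ranged from −0.00069 to 0.17. The Vps genes of vesicle sorting (31 genes, 0.08) stayed outside in 3 of the 7.

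Among the 7 low families were cell surface genes with Cd symbols (63 genes, −0.15), outside in all 7 alternatives, and genes of tissues far from the B lineage: olfactory receptors (Olfr, 409 genes, −0.33), vomeronasal receptors (Vmn, 49 genes, −0.34), cytochromes P450 (Cyp, 39 genes, −0.37), collagens (Col, 27 genes, −0.31) and keratins (Krt, 20 genes, −0.30). Olfr, Vmn and Cyp stayed outside in all 7 alternatives, Col in 6 and Krt in 4, with Olfr medians from −0.33 to −0.09. Of 886 olfactory receptor genes on the array, 409 were well above background on both arrays, at median signals of 35.5 and 33.7, where all genes had 382 and 448.

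Genes at least 2-fold different between the arrays are the first pattern weighed. A local blemish is a candidate explanation for some of them: 58.1% had a like neighbour within 3 rows and columns (62.8% of the lower genes and 34.6% of the higher). Random positions gave a median of 19.0% and an upper bound of 26.5%. Leaving out clustered spots, called whatever their own direction, still gave 21 higher and 97 lower genes, 20 and 94 of them shared with the main counts. Subtracting local medians gave 27 and 130. Artefacts of single spots stay open, since other probes had a median of 0.28 in the direction of the chosen probe over 23 genes, between the values that would decide. Eno2 and Rbbp4, both 2-fold different at a second probe, are those a follow-up might take first. Both have limits: Eno2 had low signals (37.1 and 88.2). Another probe of Rbbp4 gave −0.19, and its chosen spot lay in the later rows. Effects of BSP-II and differences between the cultures were not tested.

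The second pattern is the 4 lists at the ends of the random range: hypoxia and glycolysis, the amino acid response, G1/S and G2/M. Artefacts of the chosen probes are argued against by other probes, which only 13 of 35, 8 of 28, 11 of 39 and 7 of 34 members had: their median shift from all genes was 0.925 to 1.60 times that of all members' chosen probes. Over the same members, chosen and other probes shifted alike in 3 lists (0.19 and 0.24, 0.16 and 0.17, −0.23 and −0.25), but in G2/M the 7 members were at −0.0021 by the chosen and −0.23 by the other probes. All 4 lists stayed outside under loess and quantile scaling (4), after local medians were subtracted (4) and among genes in the earlier rows of the array (4). The first 2 checks are weak. Random lists were matched on level, so scaling by level shifts them and the lists nearly alike. Local medians had an SD of only 0.039, so subtracting them could move these 4 lists little, although the medians ranged from −0.20 to 0.17. Among all lists, 10 rather than 13 lay outside after that step. An effect of BSP-II and a treated culture that was denser or shorter of nutrients stay open and untested, since 1 culture per dose holds both.

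The third pattern lies near background: 2819 probes were well above background on the BSP-II array only and 218 on the untreated array only, a ratio of 12.9, and the chemokine list was low. With 1 shared signal floor the numbers were 629 and 1037, a ratio of 0.607, so the excess on the BSP-II array was gone; lower noise there may account for it, but the ratio fell outside the range set beforehand for that explanation, which stays open. The median of the chemokine list lay at percentile 25.7 of random lists of olfactory and vomeronasal receptor genes, but this decides nothing: those genes were taken after their like median was seen, and olfactory receptor genes had a lower median untreated signal (35.5 against 58.3). Whether signal without expression or BSP-II made the chemokine list low stays open.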
